A study of Mus musculus with 6 samples.

How the data were processed

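The data are read counts from RNA sequencing of polyadenylated RNA labelled as from mouse olfactory bulbs, 6 libraries from 3 mice. Per the labels each mouse, numbered 1037, 1038 or 1039, gave a left bulb on the side of the plugged naris and a right bulb on the open side. The library labelled left 1038 is called so throughout, since its levels go against its label. Libraries were grouped by side, and the mouse number served as the replicate.

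The deposited table gives a count of reads per gene and library, as whole numbers and with no normalization, per the file headers. The deposited table also gives an RPKM value per gene and library and a gene length, per the file headers. Recomputed from the counts, the deposited length and the library's total, each RPKM differed from the deposited one by at most 3.8e-11. The length lay within 1 base of the genomic span of the gene, introns included, for 78.41% of the genes found in the annotation, and equalled the longest transcript for 5.36%. Such RPKM values understate genes with long introns against others, so they were not used, and the comparisons rest on the counts. Per the submitters' processing notes, cutadapt 1.2.1, TopHat2, HTSeq 0.6.1p2, DESeq 1.18.0 and the genome build GRCm38 were named, with no role or order. Whether counting used the strand, and how reads of several positions were treated, is not given in the sources used here. The counts therefore do not show how reads of overlapping genes and near-identical copies were assigned. Of 147 named genes, 18 overlapped another gene of the table.

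Of the 22095 genes of the table, 21852 were matched to a symbol by their identifier, 243 were not, and 4062 had a count of 0 in all 6 libraries. Coordinates are those of GRCm38. No column of another sample was present, and 0 pairs of libraries held identical values.

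Genes were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, with TMM scaling and filterByExpr) in R 4.3.3, with side as the only term and Benjamini-Hochberg adjustment over all genes tested. Calls were made at an adjusted p under 0.05. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic of this test. All p-values are two-sided, and each adjusted p of a single gene is from this test unless another tool is named. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, for lists with at least 3 measured members, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The 30 lists, the named genes rule, the test and its alternatives were fixed before the data were examined, and the values of each list are given with the results. In the ribosomal protein list, genes that start with the prefix but encode S6 kinases or an Rps19-binding protein were left out after the data were seen.

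The labels give both bulbs of a mouse the same number, so libraries with the same number come from the same animal and are paired by design. The correlation of their deviations from the group means was 0.056, 0.047 and 0.122 in mice 1037, 1038 and 1039, and 0.277 in the 4 libraries of mice 1037 and 1039. These correlations do not decide whether a block is needed. Those of the 6 libraries include the library labelled left 1038. In the 4 libraries both mice take the same value by construction. The main fit was planned without a block although the labels pair the bulbs, so it treats both bulbs of a mouse as independent. The fit with the mouse as a block was run beside it.

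Named genes were Th, Omp, Fos, Egr1, Arc, Bdnf, Gfap and Aif1, then the 12 called genes with the largest change in each direction among those with a mean of at least 1 CPM and the same sign in each mouse. Where fewer were called, up to 6 genes with the smallest p filled the places in a direction. Up to 4 members with the smallest p were added for each list that was called or held a called gene. Genes without a name of their own were skipped in the ranking. In the 5 libraries the same rule was applied, with the sign taken in mice 1037 and 1039. Genes named outside this rule, which are Cdhr1, Cbln3, Gabra6, Fat2, Dlx1, Dlx2, Dlx5, Dlx6, Ddc, Meis2, Nr2f1, Tac1, Aldh1l1, Vim, Rps15a, the overlapping genes Capn5, Gabra4, Slc6a20a and Lztfl1, and further genes of the closing section, were chosen after their values were seen.

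The test was checked on simulated negative binomial counts with the means, dispersions and library sizes of the real data. Genes were changed 1.5-fold, 2-fold and 4-fold, and both bulbs of a mouse were drawn as independent. It recovered 0%, 4.48% and 59.1% of them in the design of 6 libraries, with 3 false calls (6.67% of calls). In the design of 5 libraries it recovered 59.7%, 88.1% and 97.0%, with 25 false calls (13.3% of calls, above the 5% aimed at).

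The alternatives were RLE size factors, total library size only, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the mouse as a block with edgeR or DESeq2, and leaving out each library or each mouse. Because the library labelled left 1038 stood apart, the planned leave-out of that library was described as a comparison of its own, a choice made after the data were seen. Where a leave-out left 1 library on a side, that library was assumed to vary like the others. The alternatives planned for a table without counts were not needed. Level plots used python 3.11.15 and matplotlib 3.10.9. Totals were 14571453 to 15590938 counts per library, so that 1 count was worth 0.0641 to 0.0686 CPM. Intervals of shares of counts are 95% Wilson intervals.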

Results

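Messenger RNA was sequenced from the olfactory bulbs of 3 outbred ICR mice. The bulb is the forebrain structure that receives the axons of the sensory neurons of the nose. The left naris of each mouse was plugged at postnatal day 30, and both bulbs were taken 60 days later. The left bulb lies on the plugged side and the right bulb of the same mouse on the open side, so each group held 3 libraries. The libraries held 14571453 to 15590938 counts over 22095 genes, and 3 counts, the limit that a count of 0 allows, corresponded to 0.192 to 0.206 CPM (counts relative to the library total). Intervals and limits of this kind cover counting error only. No mouse without a plug was among the samples, so a difference that exists between the sides without occlusion cannot be separated from one that follows it.

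The library labelled left 1038 stood apart from the other 5. Some genes of bulb neurons were close to 0 in it, while others were not, with Gad1 at 648 CPM and Reln at 435 CPM. The latter levels do not by themselves show that bulb RNA was present. Dlx1, a transcription factor of interneurons, stood at 0.618 CPM against 304 to 358 CPM in the others. Cdhr1, a marker of mitral and tufted cells, stood at 0.755 CPM against 663 to 829 CPM. Cbln3, Gabra6 and Fat2, known as genes of cerebellar granule cells, stood at 1217, 896 and 1054 CPM in this library and at 1.26 CPM or less in each of the others. Its correlation with the other libraries, across genes on the log2 CPM scale, was 0.847 to 0.855, against 0.981 to 0.992 among the others. Of genes over 20 CPM, 289 lay over 4-fold above and 479 over 4-fold below the median of the other libraries, where each of the others held at most 7 in a direction.

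**Figure D1:**
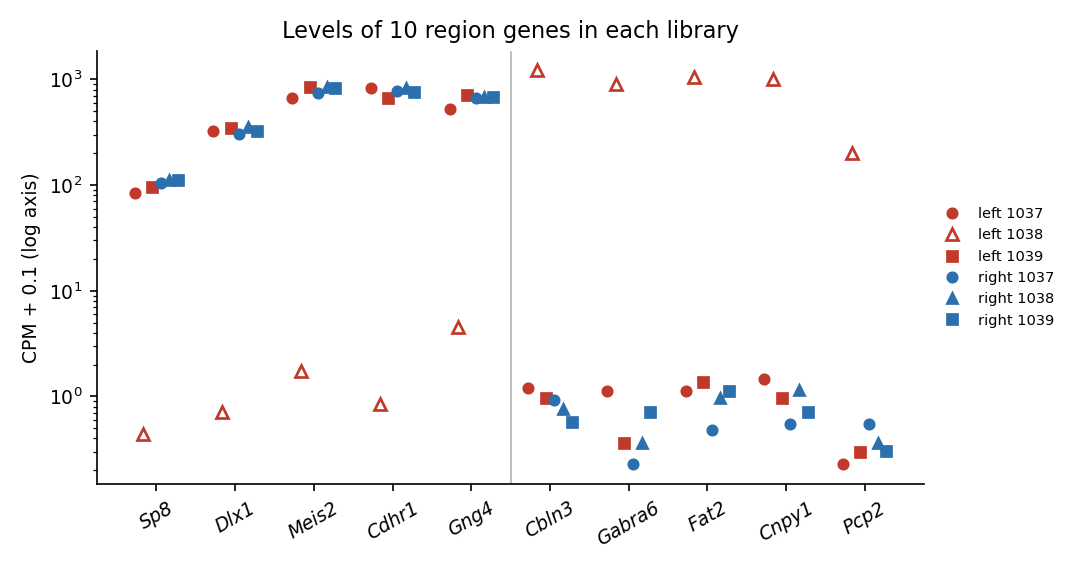
Level of 10 genes in each library, as CPM + 0.1 on a log axis. The shape gives the mouse, the colour the side, and the open triangle is the library labelled left 1038, in which Cdhr1 lay at 0.755 CPM and Cbln3 at 1217 CPM. The 5 genes left of the line are of bulb or forebrain neurons and the 5 right of it of cerebellar neurons.

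The comparison asks how the bulb on the plugged side differs from the bulb on the open side. With all 6 libraries, lists of secreted neuropeptides, of immediate early genes, of sensory neurons and of dopaminergic neurons were called lower on the left by camera with a preset correlation, while no single gene passed the test. None of these lists passed with an estimated correlation (adjusted p = 0.339 for each) or by fry (adjusted p from 0.111 to 0.163). Directions from the 6 libraries include the library labelled left 1038, whose levels go against its label. The genes with the smallest p in each direction, with the same sign in all 3 mice, are given as values. Tuba8, a tubulin, had a log2 fold change (left over right) of -0.90 (SE 0.09, adjusted p = 0.343), and Adcyap1, the precursor of the neuropeptide PACAP, had -2.55 (SE 0.26, adjusted p = 0.343). Necab3, Plagl1, Iglon5 and Dpy19l1 had -1.29, -1.0, -0.67 and -0.61. On the positive side, Id4, an inhibitor of differentiation, had 0.84 (SE 0.10, adjusted p = 0.404), and Adamts2, Per3, Sema6c, Cd44 and Rps6ka5 had 1.61, 0.67, 0.65, 1.68 and 0.73. Th, the rate-limiting enzyme of dopamine synthesis, had -2.26 (SE 0.59, adjusted p = 0.554). Omp, the olfactory marker protein of mature sensory neurons, had -3.12 (SE 1.31, adjusted p = 0.554). Fos, Egr1, Arc, Bdnf, Gfap and Aif1 had -0.72, -0.72, -1.17, -0.74, 0.56 and 0.20, with adjusted p from 0.554 to 0.907.

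Of 29 gene lists, 12 were called by camera with a preset correlation in the 6 libraries, and 0 with an estimated correlation or by fry, where 2 and 8 lay at an unadjusted p under 0.05. The median log2 fold change was -1.01 (adjusted p = 2.09e-08, and adjusted p = 0.339 with an estimated correlation) for neuropeptides and secreted factors and -0.72 (adjusted p = 8.73e-06, and adjusted p = 0.339 with an estimated correlation) for immediate early genes. It was -0.72 (adjusted p = 1.42e-04, and adjusted p = 0.339 with an estimated correlation) for sensory neurons and -0.63 (adjusted p = 0.00727, and adjusted p = 0.339 with an estimated correlation) for dopaminergic neurons. The other called lists were lower for GABAergic interneurons, GABA-A receptors, glutamate receptors, mitochondrial genes, endothelial and mural cells, cortical and striatal neurons, and higher for ribosomal proteins. For GABAergic interneurons the median was -0.56 and the mean 0.19. Adjusted over the list alone, 3 neuropeptides, 2 sensory neuron genes and 1 gene each of the GABAergic, GABA-A and glutamate receptor lists were lower, and 1 mitochondrial gene was lower and 1 higher. Of the 14209 genes tested, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05 (smallest adjusted p = 0.343), with 1196 at an unadjusted p under 0.05, while limma-voom called 0 (1166 at an unadjusted p under 0.05) and DESeq2 159, of which 36 were higher and 123 lower on the left. Without the library labelled left 1038, 1387 genes passed, and 660 passed without both bulbs of mouse 1038. That leave-out was planned, and its detailed description as a comparison of 5 libraries, 2 left and 3 right, was chosen after that library was seen.

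In these 5 libraries Th was lower and Gfap and C4b were higher in the left bulbs. Camera with a preset correlation called lists of sensory neurons, immediate early genes and secreted peptides lower and of microglia higher. With an estimated correlation none of them passed (adjusted p = 0.202, 0.243, 0.0990 and 0.243). By fry sensory neurons, secreted peptides and microglia passed (adjusted p = 0.0263, 0.01545 and 0.0462), and immediate early genes did not (adjusted p = 0.112). S100a5, a calcium-binding protein of sensory neurons (ENSMUSG00000001023, chromosome 3, 90608523 to 90611780 on GRCm38), showed the largest fall of the genes named here, with 2.58 ± 1.49 CPM on the left (SD, n = 2) and 87.0 ± 18.6 CPM on the right (SD, n = 3). On the log2 scale it fell by 5.15 (SE 0.28, adjusted p = 4.79e-05). Of 14412 genes tested, 1387 were called, 456 higher and 931 lower on the left, among them 45 over 2-fold higher and 82 over 2-fold lower. Scaled by total library size only, the split was 975 higher and 589 lower. With the mouse as a block edgeR called 1553 genes and DESeq2 429, against 1333 by DESeq2 without the block. The count was 669 without right 1037, 660 without right 1038 and 885 without left 1039, of which 639, 644 and 734 were among the 1387.

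Gal, the neuropeptide galanin, fell by 2.98 (SE 0.27, adjusted p = 5.48e-04). Adcyap1 fell by 2.34 (SE 0.15, adjusted p = 8.11e-05), and Drd1, a dopamine receptor, fell by 2.47 (SE 0.29, adjusted p = 0.00142). Htr5b, a serotonin receptor, fell by 2.18. Sfrp5 and Wif1, both secreted inhibitors of Wnt signalling, fell by 2.89 and 2.74. Tmprss11d, a serine protease, fell by 4.71, with 3 and 1 reads in the left libraries, and Cd28, a costimulatory receptor of T cells, fell by 3.47. In the other direction, Il18r1, a subunit of the interleukin-18 receptor, rose by 2.38 (SE 0.40, adjusted p = 0.00622). Cd44, the hyaluronan receptor, rose by 1.68 (SE 0.28, adjusted p = 0.00655), and Adamts2, a procollagen protease, rose by 1.36 (SE 0.13, adjusted p = 7.19e-04). Neurod1, a neuronal transcription factor, rose by 1.48 (SE 0.11, adjusted p = 2.24e-04), with 36.6 ± 0.484 CPM on the left (SD, n = 2) and 12.4 ± 1.58 CPM on the right (SD, n = 3). In the library labelled left 1038 Neurod1 stood at 518 CPM. C4b, a complement component, rose by 1.40 (SE 0.10, adjusted p = 1.56e-04). C4b lies on chromosome 17, 34728380 to 34743882, and its read count is uncertain because C4a is a near-identical copy. Spag5, Kcng1 and Npr3 rose by 1.5, 1.36 and 1.34. Gpr149, Ccr9, Upk1b and Pkhd1l1 rose by 1.76, 1.51, 1.46 and 1.34, and Frem3 and Dhrs9 fell by 2.44 and 2.05. These calls ended in leave-outs: Gpr149 (without right 1037, right 1038 or left 1039, adjusted p up to 0.0941), Ccr9 (without left 1037, right 1037, right 1038 or left 1039, adjusted p up to 0.195) and Upk1b (without left 1037, right 1037, right 1038, left 1039 or right 1039, adjusted p up to 0.214), and Pkhd1l1 (without left 1039, adjusted p = 0.0796), Frem3 (without left 1039, adjusted p = 0.0528) and Dhrs9 (without right 1037, right 1038, left 1039 or right 1039, adjusted p up to 0.215). Dhrs9 had -3.43 without left 1037 and -1.35 without left 1039. The span of Ccr9 overlaps those of Slc6a20a and Lztfl1, with means of 57 and 98.4 CPM in the 5 libraries. Ccr9 itself stood at 3.11 CPM in left 1037, so reads of these genes could bear on its value. In data simulated for this comparison the test recovered 59.7% of genes changed 1.5-fold and 88.1% of those changed 2-fold, and 13.3% of its calls were false. Far fewer genes were changed there than were called here, so these shares need not hold for the real calls.

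**Figure D2:**
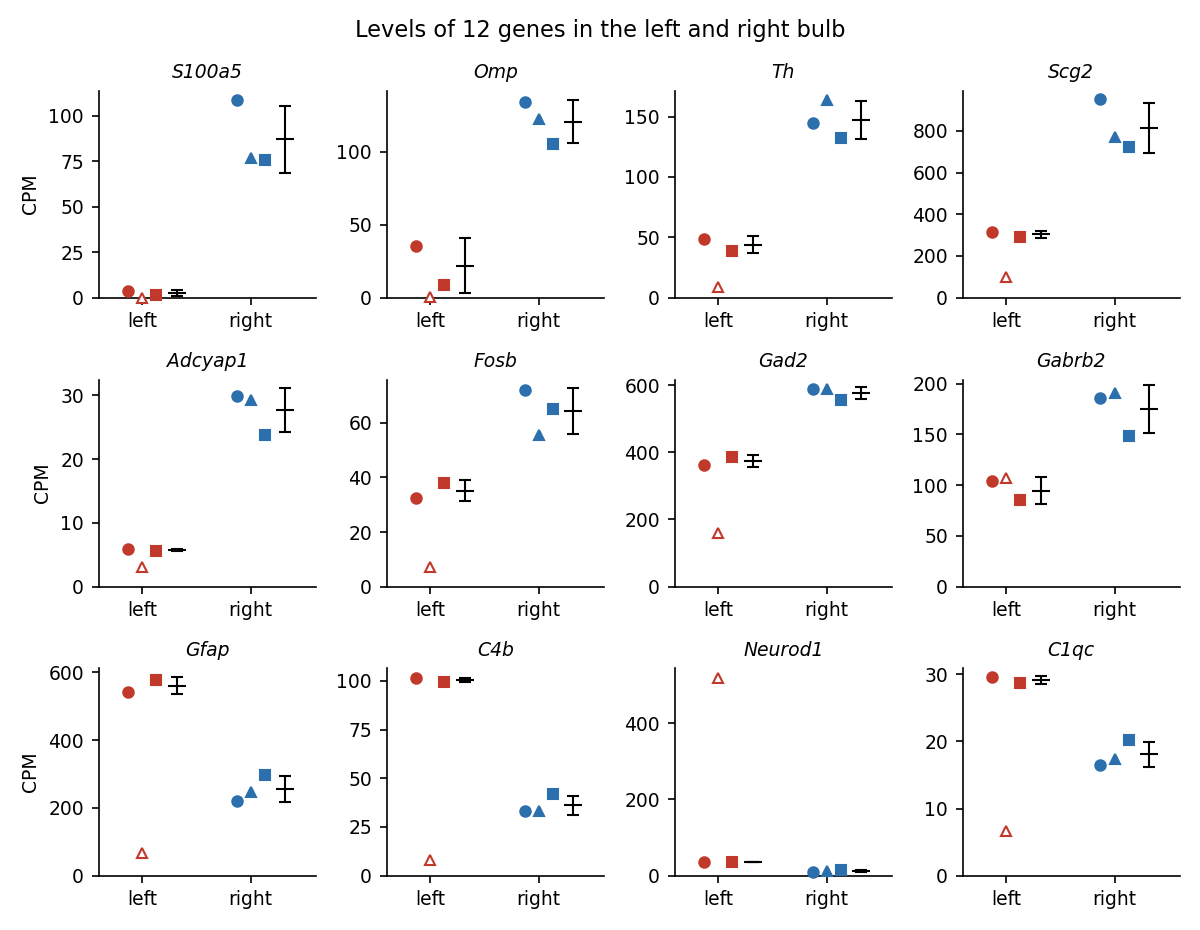
Level of 12 genes in CPM on axes that start at 0. Points are libraries (circle, mouse 1037, triangle, mouse 1038, square, mouse 1039), red on the left and blue on the right, with mean ± SD of the 5 libraries as a bar. The open triangle is the library labelled left 1038, which enters no mean, and Th lay at 44.0 CPM on the left and 147 CPM on the right.

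RNA of olfactory sensory neurons, whose axons end in the bulb, was lower on the left. Of the 12 measured genes of this list, 6 fell and 0 rose, and 8 fell and 0 rose adjusted over the list alone (median log2 fold change -0.94, camera, adjusted p = 4.12e-09, and adjusted p = 0.202 with an estimated correlation). Omp fell by 2.55 (SE 0.39, adjusted p = 0.00441), with 21.8 ± 18.9 CPM on the left (SD, n = 2) and 121 ± 14.7 CPM on the right (SD, n = 3). Omp (ENSMUSG00000074006, chromosome 7, 98143359 to 98145502) overlaps Capn5, so reads of the pair could be split between them. Stoml3, a membrane protein of sensory neurons, fell by 1.98 (SE 0.36, adjusted p = 0.00889), and Gng13, a G protein subunit, fell by 1.52 (SE 0.30, adjusted p = 0.0137). The log2 fold change of Omp was -3.92 without left 1037, that of Stoml3 -3.21 without left 1037 and -1.32 without left 1039 and that of Gng13 -2.44 without left 1037 and -0.96 without left 1039, and the list median was -0.52 without left 1039. The call of Gng13 ended without right 1037 (adjusted p = 0.0552). DESeq2 with the mouse as a block called neither Stoml3 nor Gng13 (adjusted p = 0.0631 and 0.1315), while edgeR with the block called both. The left libraries differed from each other, with Omp at 35.1 CPM in left 1037 and 8.43 CPM in left 1039. All 1088 odorant receptor genes together held 13.6 CPM (11.9 to 15.6 CPM) in left 1037 and 10.8 CPM (9.22 to 12.5 CPM) in left 1039, with 95% Wilson intervals in parentheses. In right 1037, 1038 and 1039 they held 19.4 CPM (17.4 to 21.7 CPM), 19.8 CPM (17.7 to 22.2 CPM) and 19.6 CPM (17.5 to 22.0 CPM). The library labelled left 1038 held 9.27 CPM (7.83 to 10.97 CPM), with an interval that overlaps that of left 1039. Of these genes 5 had enough counts to be tested, of which edgeR called 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.889). Markers of ensheathing cells, the glia of the olfactory nerve, were lower as a list of 7 (median log2 fold change -0.38, camera, adjusted p = 0.0131, and adjusted p = 0.494 with an estimated correlation). Of these 1 fell and 0 rose, and 3 fell and 0 rose adjusted over the list alone. The gene that fell was S100b, by 0.51, a call that ended without right 1037 or left 1039 (adjusted p up to 0.0735). The list median was -0.64 without left 1037 and -0.12 without left 1039, where the list was not called (adjusted p = 0.231).

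Th fell by 1.82 (SE 0.12, adjusted p = 8.11e-05), from 147 ± 15.9 CPM on the right (SD, n = 3) to 44.0 ± 7.08 CPM on the left (SD, n = 2). Th lies on chromosome 7, 142892752 to 142931128. Etv1 fell by 0.72 (SE 0.08, adjusted p = 9.90e-04) and Nr4a2 fell by 0.78 (SE 0.15, adjusted p = 0.0108). Pax6, Meis2 and Nr2f1, also transcription factors of the list of dopaminergic periglomerular neurons, had 0.12, -0.17 and -0.06 and did not pass. The dopamine transporter Slc6a3 had -0.76 (SE 0.23, adjusted p = 0.0727), and Ddc, which acts after Th in dopamine synthesis, had 0.17 (SE 0.16, adjusted p = 0.569). Of the 11 genes of the list, 3 fell and 0 rose, and 5 fell and 0 rose adjusted over the list alone (median log2 fold change -0.47, camera, adjusted p = 3.23e-06, and adjusted p = 0.196 with an estimated correlation).

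Activity-regulated genes were lower on the left, among them many that encode secreted factors. Of 15 neuropeptides and secreted factors, 9 fell and 0 rose, and 12 fell and 0 rose adjusted over the list alone (median log2 fold change -0.65, camera, adjusted p = 1.88e-21, and adjusted p = 0.0990 with an estimated correlation). Scg2, a secretogranin, fell by 1.5 (SE 0.11, adjusted p = 2.24e-04), with 304 ± 17.7 CPM on the left (SD, n = 2) and 816 ± 120.2 CPM on the right (SD, n = 3). Crh, corticotropin-releasing hormone, fell by 2.0 (SE 0.19, adjusted p = 6.06e-04). Bdnf, a neurotrophin, fell by 1.24 (SE 0.16, adjusted p = 0.00209), and Nptx2, a neuronal pentraxin, fell by 1.17 (SE 0.14, adjusted p = 0.00142). Tac1 was the single member above 0, with 0.56 (SE 0.29, adjusted p = 0.265). Of 16 immediate early genes, 6 fell and 0 rose, and 10 fell and 0 rose adjusted over the list alone (median log2 fold change -0.59, camera, adjusted p = 2.07e-07, and adjusted p = 0.243 with an estimated correlation). Fosb fell by 0.95 (SE 0.12, adjusted p = 0.00176), Egr2 fell by 1.03 (SE 0.18, adjusted p = 0.00775) and Homer1 fell by 0.93 (SE 0.17, adjusted p = 0.00837), and Fosl2 and Arc fell by 1.03 and 0.67. The value of Arc was -0.38 without left 1037 and -1.02 without left 1039, and the median of the immediate early genes was -0.39 without right 1037. The call of Arc ended without left 1037, right 1037 or right 1039 (adjusted p up to 0.0897). Fos had -0.62 (SE 0.19, adjusted p = 0.0693) and Egr1 -0.27 (SE 0.16, adjusted p = 0.332), and both passed with the mouse as a block (adjusted p = 6.17e-04 and adjusted p = 0.00717), also by DESeq2 (adjusted p = 0.00238 and 0.0365). With the block the side difference rests on mice 1037 and 1039 alone. Without left 1037 the value of Egr1 was 0.005.

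Gad2 fell by 0.71 (SE 0.06, adjusted p = 4.35e-04) and Gad1 fell by 0.57 (SE 0.08, adjusted p = 0.00237), the enzymes of GABA synthesis, and Slc32a1, the vesicular GABA transporter, fell by 0.46 (SE 0.08, adjusted p = 0.00768). Tpbg, a marker of a superficial granule cell type, fell by 1.0 (SE 0.12, adjusted p = 0.00164). Of 13 interneuron genes 5 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone (median log2 fold change -0.06, camera, adjusted p = 3.31e-04, and adjusted p = 0.345 with an estimated correlation), and the median was 0.02 when scaled by total library size only. It was -0.021 without left 1037, -0.10 without right 1037, -0.039 without right 1038 and -0.17 without left 1039. The transcription factors Dlx1, Dlx2, Dlx5 and Dlx6 had -0.06, 0.02, -0.03 and 0.10 and did not pass. Among 12 GABA-A receptor subunits 4 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone (median log2 fold change -0.26, camera, adjusted p = 0.00103, and adjusted p = 0.243 with an estimated correlation). Their median was -0.17 without left 1037. Gabrb2 fell by 0.97 (SE 0.12, adjusted p = 0.00164), while Gabrb1 rose by 0.36 (SE 0.06, adjusted p = 0.00475), and its span overlaps that of Gabra4. Gabrb1 was called with the mouse as a block in edgeR (adjusted p = 0.00306) but not in DESeq2 (adjusted p = 0.0609).

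Ionotropic glutamate receptors were lower as a list of 15 (median log2 fold change -0.08, camera, adjusted p = 0.00893, and adjusted p = 0.243 with an estimated correlation), with a median of 0.0027 when scaled by total library size only and of -0.046 without left 1037. Of these 5 fell and 0 rose, and 5 fell and 0 rose adjusted over the list alone. Grin3a, an NMDA receptor subunit, fell by 0.98 (SE 0.16, adjusted p = 0.00640), and Grik3, a kainate receptor subunit, fell by 0.50 (SE 0.07, adjusted p = 0.00356). Grin3a and Grin1 were not called by DESeq2 with the mouse as a block (adjusted p = 0.0778 and 0.0803), while edgeR with the block called both. Grin2a and Grin1 fell by 0.46 and 0.28, and their calls ended for Grin2a (without left 1037, adjusted p = 0.0584) and Grin1 (without right 1038, adjusted p = 0.0696). The genes of mitral and tufted cells, the output neurons of the bulb, moved both ways. Of 11 such genes 2 fell and 2 rose, and 2 fell and 2 rose adjusted over the list alone (median 0.02, adjusted p = 0.942). Cck, the cholecystokinin gene, fell by 1.07 (SE 0.11, adjusted p = 9.65e-04), and Tbx21, a transcription factor of these cells, rose by 0.65 (SE 0.11, adjusted p = 0.00580). Reln rose by 0.35 and Slc17a6 fell by 0.35, and these calls ended for Reln (without left 1037, right 1037, right 1038 or right 1039, adjusted p up to 0.208) and Slc17a6 (without left 1037, right 1037, right 1038, left 1039 or right 1039, adjusted p up to 0.143). The value of Reln was 0.20 without left 1037.

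Neuroblast genes were higher as a list of 10 (median log2 fold change 0.11, camera, adjusted p = 0.00890, and adjusted p = 0.441 with an estimated correlation), and without left 1039 the list was not called (adjusted p = 0.0703). Its median was 0.21 without left 1037 and 0.06 without left 1039. Of these 0 fell and 3 rose, and 0 fell and 3 rose adjusted over the list alone. Sox11, a transcription factor of immature neurons, rose by 0.52 (SE 0.08, adjusted p = 0.00549), while Stmn1 and Igfbpl1 rose by 0.33 and 0.47. The latter calls ended for Stmn1 (without right 1037, right 1038 or left 1039, adjusted p up to 0.0786) and Igfbpl1 (without right 1038, left 1039 or right 1039, adjusted p up to 0.127). Of 8 genes of cell division edgeR called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.649). Among 7 genes named for striatal neurons 2 fell and 0 rose, and 4 fell and 1 rose adjusted over the list alone (median log2 fold change -0.34, camera, adjusted p = 0.0291, and adjusted p = 0.243 with an estimated correlation), and without left 1037 the list was not called (adjusted p = 0.0948). The members that fell were Drd1, given above, and Pde10a, a phosphodiesterase, by 0.61, a call that ended for Pde10a (without left 1037, right 1037, right 1038 or right 1039, adjusted p up to 0.198), with a value of -0.37 without left 1037. Of 10 genes named for cortical projection neurons 2 fell and 0 rose, and 3 fell and 0 rose adjusted over the list alone (adjusted p = 0.103). Mef2c, a transcription factor, fell by 0.66 (SE 0.07, adjusted p = 0.00113), and Lamp5 fell by 0.42, a call that ended for Lamp5 (without left 1037 or right 1037, adjusted p up to 0.0757).

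Gfap, the intermediate filament protein of astrocytes, rose by 1.05 (SE 0.10, adjusted p = 6.06e-04), with 561 ± 24.6 CPM on the left (SD, n = 2) and 255 ± 38.2 CPM on the right (SD, n = 3). Gfap lies on chromosome 11, 102887336 to 102900912. Serpina3n, a secreted protease inhibitor, rose by 0.41 (SE 0.10, adjusted p = 0.0298), and Aqp4, a water channel, rose by 0.30 (SE 0.06, adjusted p = 0.0101), while S100b fell by 0.51 (SE 0.10, adjusted p = 0.0143). The 6 other astrocyte markers ranged from -0.23 for Aldh1l1 to 0.19 for Vim and did not pass. Of the 10 members 1 fell and 3 rose, and 1 fell and 3 rose adjusted over the list alone (median log2 fold change 0.06, camera, adjusted p = 0.0419, and adjusted p = 0.494 with an estimated correlation). The list median was 0.011 without left 1037 and 0.13 without left 1039. The list was not called without left 1037 (adjusted p = 0.224) or right 1037 (adjusted p = 0.0987), and single calls ended for Serpina3n (without left 1037, right 1037, left 1039 or right 1039, adjusted p up to 0.102), Aqp4 (without mouse 1037, adjusted p = 0.0653) and S100b (without right 1037 or left 1039, adjusted p up to 0.0735).

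Microglial genes were higher on the left as a list of 14 (median log2 fold change 0.33, camera, adjusted p = 1.27e-05, and adjusted p = 0.243 with an estimated correlation). Of these 0 fell and 4 rose, and 0 fell and 8 rose adjusted over the list alone, and 13 lay above 0. C1qc rose by 0.61 (SE 0.11, adjusted p = 0.00775), C1qb rose by 0.56 (SE 0.11, adjusted p = 0.0156) and C1qa rose by 0.45 (SE 0.11, adjusted p = 0.0290), the subunits of complement C1q, and Ctss, a lysosomal protease, rose by 0.57 (SE 0.10, adjusted p = 0.00966). The calls of the former ended for C1qb (without left 1037 or right 1038, adjusted p up to 0.0948) and C1qa (without left 1037, right 1038 or right 1039, adjusted p up to 0.119). By DESeq2 with the mouse as a block none of C1qc, Ctss, C1qb and C1qa was called (adjusted p = 0.191, 0.0997, 0.403 and 0.493). Aif1, which encodes the microglial protein IBA1, had 0.65 (SE 0.23, adjusted p = 0.108). The list of phagocytic microglia moved both ways, where 2 fell and 1 rose of 9, and 3 fell and 1 rose adjusted over the list alone (median 0.08, mean -0.01, adjusted p = 0.773). Spp1, the osteopontin gene, fell by 0.65 (SE 0.11, adjusted p = 0.00731), and Gpnmb fell by 1.07, a call that ended for Gpnmb (without right 1038 or left 1039, adjusted p up to 0.0624). Tyrobp rose by 0.59 (SE 0.14, adjusted p = 0.0336), and it was not called with the mouse as a block in edgeR (adjusted p = 0.0525) or DESeq2 (adjusted p = 0.734) or without any 1 of the 5 libraries (adjusted p up to 0.142).

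Genes of antigen presentation were higher as a list of 8 (median log2 fold change 0.40, camera, adjusted p = 8.56e-05, and adjusted p = 0.202 with an estimated correlation). Of these 0 fell and 3 rose, and 0 fell and 7 rose adjusted over the list alone. Cd74, the invariant chain of class II molecules, rose by 1.02 (SE 0.19, adjusted p = 0.0109), and H2-K1 and H2-D1 rose by 0.49 and 0.28, with reads that near-identical genes of this family could share. These calls ended for Cd74 (without left 1037, adjusted p = 0.0619), H2-K1 (without right 1037, right 1038 or left 1039, adjusted p up to 0.159) and H2-D1 (without right 1037, right 1038 or left 1039, adjusted p up to 0.155). Of 9 genes of the interferon response 0 fell and 1 rose, and 0 fell and 1 rose adjusted over the list alone (median log2 fold change 0.35, camera, adjusted p = 0.0236, and adjusted p = 0.243 with an estimated correlation), and the list was not called without left 1037 (adjusted p = 0.161). The member that rose was Oasl2, an interferon-induced gene, by 0.72, a call that ended without any 1 of the 5 libraries (adjusted p up to 0.114). Of 6 genes of inflammation and complement 1 fell and 1 rose, and 1 fell and 1 rose adjusted over the list alone (median log2 fold change 0.38, camera, adjusted p = 0.0131, and adjusted p = 0.243 with an estimated correlation), with a median of 0.60 without left 1039. With no filter camera did not call this list (adjusted p = 0.0501). The genes called were C4b, given above, and Ptgs2, a cyclooxygenase, which fell by 1.20, a call that ended for Ptgs2 (without right 1037 or left 1039, adjusted p up to 0.0674).

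**Figure D3:**
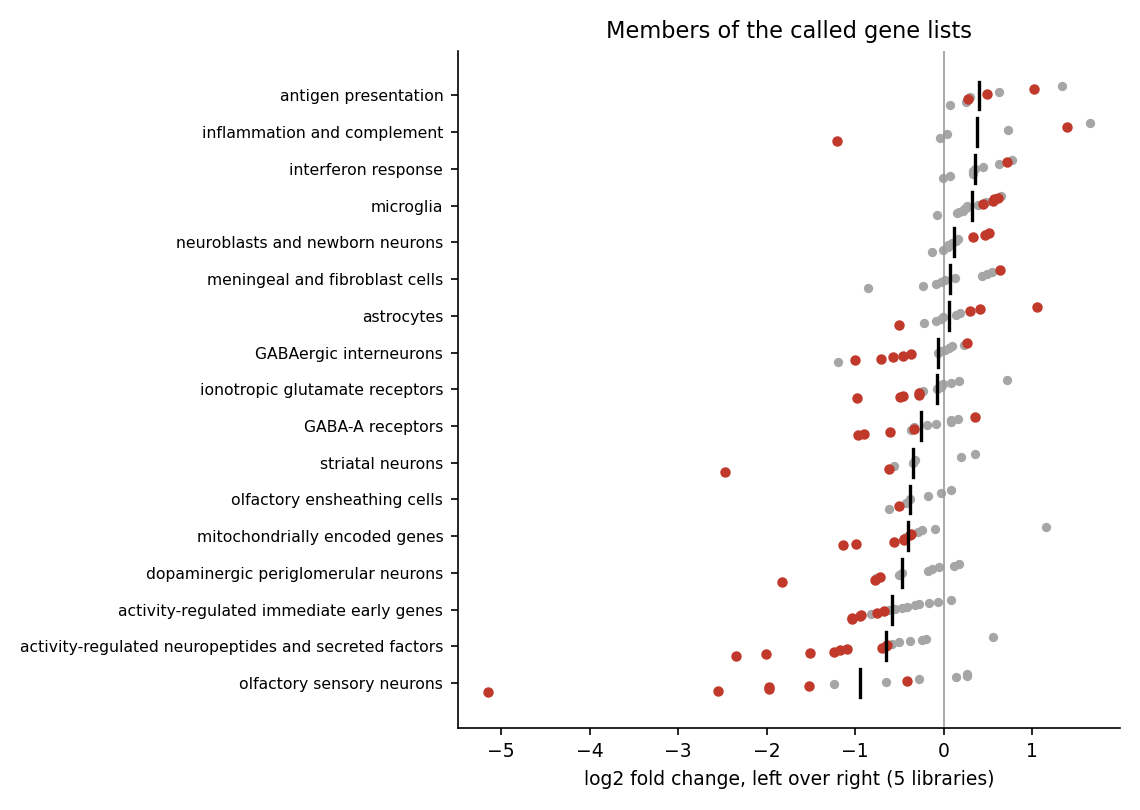
Log2 fold change, left over right in the 5 libraries, of each measured member of 17 of the 18 called gene lists. Red points passed the test, grey points did not, and the black bar is the list median, from -0.94 for olfactory sensory neurons to 0.40 for antigen presentation. The medians of GABAergic interneurons and ionotropic glutamate receptors are above 0 when scaled by total library size only, and ribosomal proteins are not drawn.

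Transcripts of the mitochondrial genome took less of the counts on the left. Their share was 4.35% (4.34% to 4.36%) in left 1037 and 3.63% (3.62% to 3.64%) in left 1039, with 95% Wilson intervals in parentheses. In right 1037, 1038 and 1039 it was 5.09% (5.08% to 5.11%), 4.94% (4.93% to 4.95%) and 5.11% (5.09% to 5.12%), and in the library labelled left 1038 4.37% (4.36% to 4.38%). Of 12 genes 7 fell and 0 rose, and 8 fell and 1 rose adjusted over the list alone (median log2 fold change -0.41, camera, adjusted p = 5.00e-06, and adjusted p = 0.243 with an estimated correlation). mt-Nd5, a subunit of complex I, fell by 0.56 (SE 0.09, adjusted p = 0.00504), and mt-Nd6, which overlaps mt-Nd5 on the other strand, fell by 1.14. Genes of ribosomal proteins took 1.20% (1.19% to 1.21%) and 1.27% (1.26% to 1.28%) of counts in left 1037 and left 1039. In right 1037, 1038 and 1039 they took 1.07% (1.06% to 1.07%), 1.12% (1.12% to 1.13%) and 1.06% (1.05% to 1.06%), and in the library labelled left 1038 1.03% (1.02% to 1.03%), below right 1038. Of 82 measured, 0 fell and 1 rose, and 0 fell and 0 rose adjusted over the list alone (median log2 fold change 0.11, camera, adjusted p = 1.73e-05, and adjusted p = 0.494 with an estimated correlation). The gene that rose was Rps15a, by 0.23. Without mouse 1039 the list was not called (adjusted p = 0.102).

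Meningeal and fibroblast genes were higher as a list of 10 (median log2 fold change 0.07, camera, adjusted p = 0.0291, and adjusted p = 0.494 with an estimated correlation), and the median was -0.30 without left 1037, 0.31 without right 1038, 0.39 without left 1039 and 0.16 without right 1039, with the list not called without left 1037 (adjusted p = 0.926). Of these 0 fell and 1 rose, and 0 fell and 2 rose adjusted over the list alone. Igf2, an insulin-like growth factor, rose by 0.64 (SE 0.08, adjusted p = 0.00162), while Slc6a13, a GABA transporter, had 0.55 (SE 0.16, adjusted p = 0.0678) and passed with the mouse as a block in edgeR (adjusted p = 0.0308) but not in DESeq2 (adjusted p = 0.4997). Of 6 choroid plexus genes 0 fell and 2 rose, and 0 fell and 2 rose adjusted over the list alone (median 0.53, adjusted p = 0.105). Ttr, the transthyretin gene, stood at 171 CPM in left 1037, at 7.10 CPM in left 1039 and at 6.72 ± 0.904 CPM on the right (SD, n = 3). Its value of 3.65 rested on left 1037, and it was 4.20e-04 without left 1037 and -0.10 without mouse 1037. Kl rose by 0.95, with 0.48 without left 1037, and both calls ended in leave-outs, for Ttr (without left 1037, right 1037, right 1038 or right 1039, adjusted p up to 0.999) and Kl (without left 1037, right 1037, right 1038 or right 1039, adjusted p up to 0.303). Of 12 endothelial and mural genes 2 fell and 0 rose, and 2 fell and 0 rose adjusted over the list alone (adjusted p = 0.172). Kdr, a receptor of vascular endothelial growth factor, fell by 0.58 and Vtn by 0.54, calls that ended for Kdr (without right 1038, left 1039 or right 1039, adjusted p up to 0.103) and Vtn (without right 1037, right 1038, left 1039 or right 1039, adjusted p up to 0.101). The value of Vtn was -0.85 without left 1037 and -0.28 without left 1039.

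Of 12 genes of the oligodendrocyte lineage 2 fell and 0 rose, and 3 fell and 0 rose adjusted over the list alone (adjusted p = 0.0634, and adjusted p = 0.00743 with the mouse as a block). Olig1, a transcription factor of the lineage, fell by 0.38 and Pdgfra, a receptor of its precursor cells, fell by 0.36, calls that ended for Olig1 (without right 1037, left 1039 or right 1039, adjusted p up to 0.102) and Pdgfra (without right 1038, left 1039 or right 1039, adjusted p up to 0.105). Of 13 apoptosis genes 2 fell and 0 rose, and 2 fell and 3 rose adjusted over the list alone (median 0.20, adjusted p = 0.431). Cycs, the cytochrome c gene, fell by 0.34 (SE 0.06, adjusted p = 0.00641), and Bcl2, an inhibitor of cell death, fell by 0.43, a call that ended for Bcl2 (without right 1037, right 1038 or left 1039, adjusted p up to 0.113). Bbc3, which promotes cell death, had 0.66 (SE 0.19, adjusted p = 0.0525) and passed with the mouse as a block in edgeR (adjusted p = 0.0193), where DESeq2 gave no adjusted p. Cycs and Bcl2 were called with the block in edgeR but not in DESeq2 (adjusted p = 0.0672 and 0.294). Of 11 genes of heat shock and endoplasmic reticulum stress, 3 blood genes and 4 sex-linked genes edgeR called 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05. The adjusted p of these lists was 0.942, 0.558 and 0.486.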

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

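The alternatives of the 6 libraries were planned, and the tests of all alternatives of the 5 libraries were chosen after the results were seen. In the 6 libraries the count of 0 genes (edgeR, 1196 at an unadjusted p under 0.05) was the same with the mouse as a block (671), RLE size factors, total library size only, no filter, the 1 CPM filter and limma-voom (1166). DESeq2 called 159 (36 higher, 123 lower), and 25 (3 higher, 22 lower) with the replicate block. Leave-outs gave 0 to 1666 genes, 0 to 573 higher and 0 to 1093 lower, all above 0 only without left 1038 or mouse 1038, and 8 to 19 of the gene lists against 12. Lists called were 0 with an estimated correlation and 0 with fry. Of the named genes, Gfap ranged over leave-outs from -0.50 to 1.05, with -0.34 in the blocked fit without mouse 1039. Aif1 was -0.072 with the block, -0.090 by DESeq2 with the block and -0.10 by limma-voom, and ranged over leave-outs from -0.51 to 0.65, with -0.30 without left 1039, -0.42 and -0.18 without mouse 1037 (blocked) and 1039. With the mouse as a block 9 lists were called, without striatal neurons, glutamate receptors and ribosomal proteins (adjusted p = 0.0754, 0.0829 and 0.0545), and no call of a named gene changed. DESeq2 and limma-voom gave no list test here.

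In the 5 libraries the count of 1387 genes was 1553 with the replicate block (1258 shared, each in the same direction), 1333 with DESeq2 and 1392 with limma-voom, and 429 (74 higher, 355 lower) with DESeq2 and the block. Total library size only gave 975 higher and 589 lower, with a median over all genes of 0.09. Leave-outs gave 660 to 1706 genes, 172 to 625 higher and 479 to 1081 lower. Lists called were 18, 0 with an estimated correlation, 9 with fry, 14 to 19 in leave-outs and 19 with the block. The lower lists that passed by fry were sensory neurons, neuropeptides and secreted factors, dopaminergic neurons, striatal neurons and glutamate receptors. The higher ones were microglia, antigen presentation, inflammation and complement, and interferon response (adjusted p for all from 0.01545 to 0.0462). The other called lists did not pass by fry (adjusted p from 0.0593 to 0.290). In edgeR the block changed no other call of a list or named gene than those given beside their results and those of Frzb, Fabp7 and Nrep. The latter passed with it (adjusted p = 0.0277, 0.0145 and 0.0336). In DESeq2 with the block Frzb, Fabp7 and Nrep did not pass (adjusted p = 0.848, 0.839 and 0.327). It gave no adjusted p for 31 of the 119 named genes, and of 67 called by edgeR that had one, 25 were not called. Among these, 6 were called in each leave-out, C1qc, Ctss, Stoml3, Grin3a, Gabrb1 and Cycs (adjusted p = 0.191, 0.0997, 0.0631, 0.0778, 0.0609 and 0.0672). The others were Slc17a6, Reln, Igfbpl1, C1qb, C1qa, Tyrobp, H2-K1, H2-D1, Aqp4, Serpina3n, Olig1, Pdgfra, Gng13, Kdr, Vtn, Ttr, Lamp5, Grin1 and Bcl2 (adjusted p from 0.0780 to 0.813). List medians that turned were GABAergic interneurons, 0.023, and ionotropic glutamate receptors, 0.0027, with total library size only. Astrocytes ranged over leave-outs from -0.0080 to 0.14, and meningeal cells from -0.32 to 0.44. Interferon response and meningeal cells were not called with total library size only (adjusted p = 0.0669 for both), nor inflammation and complement with no filter (adjusted p = 0.0501). Egr1 ranged over leave-outs from -0.60 to 0.0050 and Ttr from -0.10 to 4.66. Of 89 named genes called, 46 were called in each alternative that gave a value and 52 in each leave-out. The cause was not tested, except that leave-outs hold fewer samples. At this depth 5 of the 1088 odorant receptors had enough counts to be tested.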

Other observations

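The 3 gene lists of the next paragraph were written after the data were seen, and the tests of mixed tissue, of more astrocytes, of an equal loss of sensory neuron RNA and of the splits of 5 libraries were chosen after their results were seen. The reading of the nerve layer test was changed after its value was seen, from against to open and back.

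Of 17 target and feedback genes of ERK signalling, 12 fell and 0 rose in the 5 libraries (median log2 fold change -0.72). Ccnd1, the cyclin D1 gene, fell by 1.20 (SE 0.13, adjusted p = 0.00113), and Dusp6, a phosphatase of ERK, fell by 0.85 (SE 0.10, adjusted p = 0.00131). Spry4, an inhibitor of receptor tyrosine kinase signalling, fell by 0.93 and Etv5 by 0.76. Of 14 genes of dense-core vesicles, which store peptides, 9 fell and 0 rose (median log2 fold change -0.29). Pcsk1, a prohormone convertase, fell by 1.33 (SE 0.16, adjusted p = 0.00148), and Ptprn, a vesicle membrane protein, fell by 0.83 (SE 0.06, adjusted p = 2.13e-04), while Chgb fell by 0.59. Scg2 and Vgf stand in this list and in that of activity-regulated secreted factors, and Etv1 in the ERK and dopaminergic lists. Of 14 circadian clock genes 1 fell and 4 rose (median log2 fold change 0.15). Per3 rose by 0.63 (SE 0.07, adjusted p = 0.00142), with a span that overlaps Camta1, and Tef and Dbp rose by 0.37 and 0.34, while Npas2 fell by 0.75 (SE 0.12, adjusted p = 0.00452). The lists were written from the same libraries, so no test of them as lists is given, and no leave-outs of them were run.

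The library labelled left 1038 held little RNA of 12 bulb genes, which were picked from it for that. Their median lay at 0.195% of the level in the other libraries (highest 0.647%), which is low by the way they were picked. A mixture with at least 10% bulb RNA like that of the other libraries would leave no bulb gene under 10%, however picked. The values therefore argue against such a mixture, while a smaller share of bulb RNA was not tested. A stronger response to occlusion of the kind in the other mice is also argued against. For this, 7 cerebellar genes were chosen as over 4-fold higher on the left in mouse 1038, where their median left to right difference was 3.04 (log2). In mice 1037 and 1039 these genes had a median of 0.10 (range -0.46 to 0.71), which that choice does not set. Of 9 cerebellar genes not looked at before, 6 lay over 4-fold above the highest other library, 6 of the 9 are also over 10 CPM in another library, 3 forebrain genes lay at 0.475% in median, and 0 of 39 Hox genes lay over 1 CPM. Hox genes lay at 0.398 CPM or less in the other libraries too, so they do not separate bulb from cerebellum. The values of the cerebellar and forebrain genes go with RNA of cerebellum in place of bulb RNA. Whether this came through an exchanged sample or label or in another way was not tested and stays open.

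Gfap rose by 1.05 in the 5 libraries, and 2 explanations were weighed. More astrocytes would raise their other markers by a like amount, and the median of the other 9 markers was -0.0086 (median absolute deviation 0.292, scaled to stand for an SD), which argues against it. A reactive state of astrocytes may raise Gfap with other reactive genes, and of 14 such genes not looked at before, 5 rose and 0 fell, with a median of 0.229 (camera, p = 0.00135, and p = 0.0422 with an estimated correlation). That median lies between the bounds set in advance for and against, so this explanation stays open. The 5 were Ggta1, Aspg, Gbp2, Emp1 and Osmr, which rose by 1.26, 1.07, 0.74, 0.69 and 0.64.

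S100a5 fell more than Omp, although both are genes of sensory neurons. An equal loss of all sensory neuron RNA would keep their ratio, and the ratio of S100a5 to Omp was 0.116 and 0.227 in left 1037 and 1039 against 0.628 to 0.808 on the right, a log2 difference of -2.14. The ratio restates, library by library, the larger fall that raised the question, so it is no separate evidence. An equal loss would still not give these values. Less olfactory nerve layer at dissection could lower both, and 5 ensheathing cell genes not looked at before had a median of -0.48 (range -0.53 to 0.50). That median lay above the bound of -0.5 set in advance against this explanation by less than their unscaled median absolute deviation of 0.0493. Each gene lay above the -1 that the explanation needs by over 2 SE, a criterion added after the value was seen. That loss would also keep the ratio, so the values argue against it as the whole cause, while a smaller loss stays open. Lower expression of S100a5 in the neurons that remain is a candidate explanation that the tables do not exclude and that no test here measured.

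Of the 10 splits of the 6 libraries into groups of 3, which are too few for a share under 0.05, 10 gave as many genes as the real one, itself included. EdgeR called 0 for the real split (1196 at an unadjusted p under 0.05, with 159 called by DESeq2 and 0 by limma-voom) and 0 for the highest other, also where both bulbs of each mouse were parted. Of the 10 splits of the 5 libraries, also too few for a share under 0.05, 1, the real one, gave as many as its 1387 genes. The highest other, both bulbs of mouse 1039 against the rest, called 7. Each other split put left and right bulbs in the same group, so a difference between the sides widens the spread within its groups. Their counts are therefore not those of libraries without such a difference.

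Across genes, which are not independent replicates, the left to right differences of mice 1037 and 1039 had a Pearson correlation of 0.494, and those of mouse 1038, with the library labelled left 1038, had 0.173 and 0.189 with them.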
